A study of Homo sapiens with 6 samples.

How the data were processed

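RNA was profiled from MCF-10A cells, an established line of non-tumorigenic human breast epithelial cells, on 6 Illumina HumanHT-12 bead arrays. Per the labels, the cells stably carried either the empty retroviral vector pMSCV or pMSCV with GNA13 and were kept under blasticidin selection before seeding. Each group had 3 arrays, numbered 1 to 3 in the sample titles. Nothing in the labels says that the 3 arrays of a group came from separate cultures or separate selections, so p-values measure the spread between these samples, which may be partly technical. Per the labels' protocols, total RNA was column-purified and DNase-treated, and biotinylated cRNA was made with an amplification kit for Illumina arrays.

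The deposited values were of 3 kinds. The non-normalized intensity of each of 47323 probes was deposited with its standard error over beads and its number of beads, per the file headers. The deposited detection p-value of each probe took steps of 1 in 770, as a rank among negative control beads gives. The authors' processed intensity values were also deposited. Within each array they had the same rank order as the non-normalized values, and their distributions were nearly equal between arrays. They were thus quantile normalized, on a linear scale, with no background subtracted. The arrays' medians were 136 in all 6 columns of that matrix. The match of ranks also tied each non-normalized column, named for control or G13 and a number, to its sample. The scanner software and its version are not given in the sources used here. The authors' deposited table of comparisons held a linear ratio (fold) of GNA13 over control and a p-value per gene, per the file headers, for 16383 genes. Its F values and sums of squares fit an analysis of variance with 3 and 8 degrees of freedom, or with multiples of these. It would thus have used 12 arrays in 4 groups, or more, and at least 6 of those arrays are not analysed here. It was sorted by the overall p-value and ended at an overall p of 0.152.

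From the non-normalized intensities, background was corrected with the normexp model, with the background's mean and spread estimated from the detection p-values. Signals were then quantile normalized, raised by an offset of 16 and put on the log2 scale, in R 4.3.3 with limma 3.58.1. A probe was kept where its detection p was under 0.05 on at least 3 of the 6 arrays, whatever their group, which left 19834 probes. Over all probes, the platform annotation gave 1 gene symbol for 30113 probes, several for 8 and none for 17202. Probes with several symbols were not used, and those without a listed gene were tested apart. The brightest kept probe over all 6 arrays stood for each gene, which gave 11342 genes. All but 6 of their symbols were found in the RefSeq gene table of assembly GRCh38.p14, and none needed an update. That table served only for names and for the order of neighbouring genes, and no positions on the genome are given here. Of 1114 further kept probes of the changed genes, 942 (84.6%) had the sign of the probe used.

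Groups were compared with limma's moderated test (lmFit and eBayes, two-sided, group as the only term) and Benjamini-Hochberg adjustment over all genes tested, with an adjusted p under 0.05 as the threshold. The GNA13 probes were each tested in a fit over all kept probes with 1 gene symbol. "Rose", "fell" and "changed" refer to that threshold. Log2 fold changes are GNA13 minus vector and are given with their standard error (SE), with n = 3 arrays per group. Where the probe used for a gene was not detected on any array of a group, the fold is a bound. It sets the bright group's mean against the mean of the lowest normalized signal among detected probes, per array, or the probe's own signal where that was higher. Folds and bounds hold only under the background correction used. With none, the folds of 20 of 104 changed genes taken by the naming rule below were over 1.5 times smaller, and no fold was larger. Gene lists were tested with camera, which compares a list's shift with that of other genes, with a preset correlation of 0.01, and adjusted over the 29 lists with at least 5 measured genes. The result of 1 of these lists is not reported here. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run as alternatives. Of the 13 lists past the threshold with the preset correlation, 3 stayed past it with an estimated one, the kallikreins, the epithelial junction genes and the cornified-envelope genes. The 30 gene lists, the tests, most of the other settings tried and the rule for naming genes were fixed before the data were examined. The rule took GNA13, every measured kallikrein, the 10 largest rises and the 10 largest falls whose groups did not overlap, and the 3 largest changes of each list. Any other gene named was chosen after its values were seen. The list of kallikreins is remembered to have been chosen by the study on these samples and is not independent evidence of its direction.

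The procedure was tested on simulated arrays with 200 changed probes and 12432 genes tested. It recovered 62.5% of genes changed by 0.5 on the log2 scale, 98.0% of those changed by 1 and all of those changed by 2 or 3. Of its calls, 8.99% were false. A far smaller share of genes changed in the simulation than in the data, so these percentages need not hold for the data. Alternatives were other filters on dim probes, no background correction, another offset, 2 other normalizations, the authors' processed values, the mean of a gene's probes, another variance model, the replicate number as a block and each array left out in turn. The number of arrays limits the precision. No array was left out of the main comparison. No array was a copy of another of its group, since 0 of the 19834 kept probes had identical values in any pair within a group. Those pairs differed by 1.35 to 2.07 bead standard errors. Figures were drawn with matplotlib.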

Results

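The data described how the transcripts of MCF-10A breast epithelial cells differed when GNA13 was introduced. GNA13 encodes the alpha subunit of the heterotrimeric G protein G13, which relays signals from cell-surface receptors. The 3 arrays of cells with the empty vector detected 19127, 19669 and 19270 of the 47323 probes, and the 3 arrays of GNA13 cells detected 19662, 19876 and 20015. Median raw intensity lay between 129 and 141 on all arrays, with a median of 20 to 21 beads behind each value. Log2 intensities correlated across probes with r of 0.993 to 0.995 between arrays of a group and 0.976 to 0.978 between groups. The first principal component held 70.6% of the variance and separated the groups.

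The endogenous and introduced GNA13 transcripts could be read only through 2 probes, both detected on all 6 arrays. The brighter probe had a log2 intensity of 9.64 ± 0.09 in vector cells and 9.89 ± 0.14 in GNA13 cells (SD, n = 3 each). This is a fold of 1.18 with a 95% confidence interval of 1.00 to 1.39 (limma adjusted p = 0.128 over the 15111 kept probes with 1 gene symbol and 0.114 over genes). The other probe read 8.35 ± 0.16 and 8.47 ± 0.08, a fold of 1.09 with an interval of 0.922 to 1.29 (limma adjusted p = 0.423 over the same probes). Neither probe passed the threshold. Where the probes lie in the transcript was not known here, and a probe outside the introduced coding sequence would not measure it.

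The GNA13 cells had far more transcript of several secreted, matrix and receptor genes. ACKR1, a decoy receptor for chemokines, was not detected on any vector array and was at least 23.6-fold higher in GNA13 cells (limma adjusted p = 6.14e-07, log2 intensity 10.30 ± 0.11 SD against a probe signal of 5.19 ± 0.22). The adhesion molecule CADM3, detected on 1 of the 3 vector arrays and so set against signals near background there, rose by a log2 fold change of 4.56 ± 0.14 (SE), and the proteoglycan core protein SRGN by 4.30 ± 0.11. ROS1, a receptor tyrosine kinase, and WNT5A, a secreted Wnt ligand, were also not detected in vector cells and were at least 9.25-fold and at least 7.03-fold higher. The secreted protease HTRA1 rose 10.9-fold, the matrix proteoglycan DCN 10.5-fold, and the collagen chains COL6A3 and COL8A1 9.47-fold and 8.40-fold. RTN1 was at least 8.08-fold higher on the probe used, which no vector array detected. Its other probe differed by only 0.30 on the log2 scale. With any single GNA13 array left out, the probe used no longer passed the detection filter, and on the other probe the call was lost (0.31, 0.29 and 0.29 without GNA13 arrays 1, 2 and 3). The size of several of these rises rests on the background correction. Without it, all stayed past the threshold, but CADM3 and SRGN had log2 fold changes of 3.07 and 3.46, and ACKR1 was 10.7-fold, DCN 5.69-fold, ROS1 4.70-fold, RTN1 3.84-fold and WNT5A 3.78-fold higher. HTRA1, COL6A3 and COL8A1 depended on it less, at 8.25-fold, 7.68-fold and 7.75-fold higher without it.

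Keratin and kallikrein transcripts were among the largest falls. COXFA4L3 had a log2 fold change of −3.68 ± 0.12 (SE), a 12.9-fold difference, with detection on 2 of the 3 GNA13 arrays and so against signals near background. The calpain-family gene CAPN13, the FGF-binding protein FGFBP1 and the GABA-A receptor subunit GABRP were not detected on any GNA13 array and were at least 5.92-fold, 5.84-fold and 5.10-fold lower. KRT13, a keratin of stratified epithelia, fell 6.30-fold, the guanylate-binding protein GBP6 6.37-fold and the glucose transporter SLC2A12 6.07-fold. GBP6 was detected on 2 and SLC2A12 on 1 of the 3 GNA13 arrays, so these folds are set against signals near background. KRT16P2 read 5.74-fold lower, but it is a pseudogene of KRT16 and the array may not separate the pair. KLK8 and KLK10 complete the 10 largest falls. Without background correction, COXFA4L3 was 5.04-fold, CAPN13 3.47-fold, FGFBP1 3.12-fold, GABRP 2.93-fold, GBP6 2.83-fold and SLC2A12 2.69-fold lower.

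In all, 3105 of 11342 genes (27.4%) changed, 1555 higher and 1550 lower in GNA13 cells, and 4440 had an unadjusted p under 0.05. At least 1.5-fold changes were seen in 1239 of them, 602 higher and 637 lower. At least 4-fold, 32 were higher and 27 lower. Among the changed genes, 3100 had groups that did not overlap. This held for 44.1% of all genes tested, where chance gives 10%. Of the changed genes, 87 were not detected by any probe on a vector array and 43 not on a GNA13 array. With median scaling in place of quantile normalization, 2007 genes changed, 1148 higher and 859 lower. The count of genes higher dropped to 977, 986 and 985 when GNA13 array 1, 2 or 3 was left out.

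Kallikreins are secreted serine proteases encoded in one gene cluster. Of 7 measured, 6 fell and none rose (7 fell adjusted over the list alone), with a median log2 fold change of −1.88 (camera adjusted p = 2.62e-08; adjusted p = 0.0358 with an estimated correlation). The study is remembered to have picked this list from these samples, so neither count is independent evidence of its direction. KLK10 fell 6.23-fold (log2 fold change −2.64 ± 0.07 SE), KLK6 4.01-fold, KLK7 3.67-fold and KLK5 3.42-fold. KLK7 was among the bright transcripts, at a log2 intensity of 14.02 ± 0.16 in vector cells and 12.14 ± 0.18 in GNA13 cells (SD). KLK8 and KLK11 were not detected by the probe used on any GNA13 array and were at least 8.22-fold and 1.51-fold lower. KLK1, near background, had a log2 fold change of −0.57 ± 0.23 and did not pass. Second probes of KLK6, KLK8 and KLK10 differed by less, with log2 fold changes of −0.33, −0.76 and −0.06. Each was dimmer than the probe used, but whether low signal accounts for the smaller falls was not tested. Another KLK8 probe was detected in GNA13 cells, where the probe used was not. The size of these 3 falls thus depends on the probe. Other probes of KLK5 (−2.26 and −1.92) and KLK7 (−2.39) fell further than the probes used (−1.78 and −1.88). With any single vector array left out, the KLK8 probe used no longer passed the detection filter. On the other probe the call was lost without vector array 2 or 3, at −0.69 and −0.79. Without vector array 1 the call held on that other probe, at −0.84. KLK8 was 3.88-fold lower with no background correction.

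**Figure D1:**
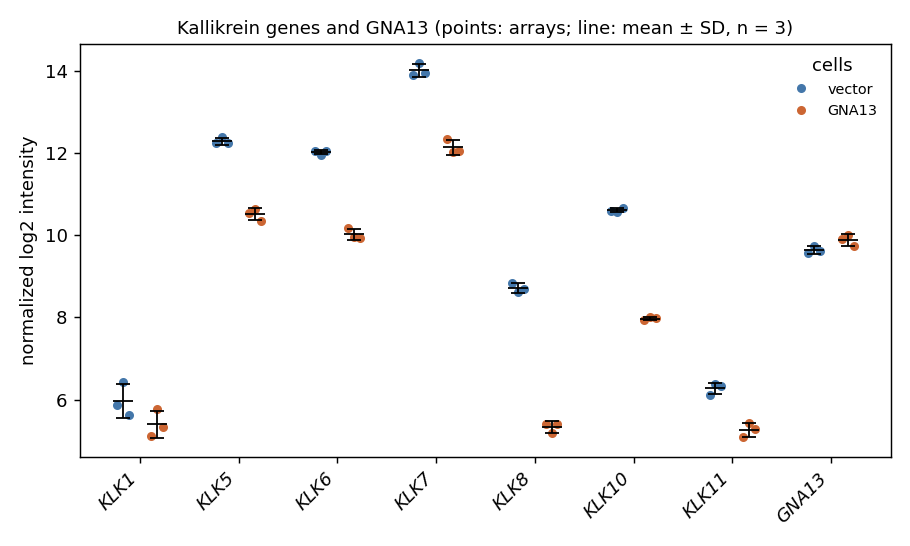
Normalized log2 intensity (vertical axis) of the 7 measured kallikrein genes and GNA13 (horizontal axis) in vector and GNA13 cells. Points are single arrays and lines are means ± SD (n = 3). KLK5, KLK6, KLK7, KLK8, KLK10 and KLK11 lie lower on all 3 GNA13 arrays, and GNA13 itself differs by 0.24.

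Genes of epithelial junctions and epithelial identity fell as a group. Of 33 measured, 29 fell and none rose (29 adjusted over the list alone), with a median log2 fold change of −0.80 (camera adjusted p = 1.54e-17; adjusted p = 0.0344 with an estimated correlation). The epithelial transcription factor ELF3 fell 5.14-fold (log2 fold change −2.36 ± 0.16 SE), the tight-junction protein CLDN1 3.18-fold and the polarity protein CRB3 2.73-fold. CDH1, which encodes E-cadherin, fell by 0.98 ± 0.08 and EPCAM fell by 0.69 ± 0.08. The members that did not pass were TJP1, DSG2, CTNNA1 and CTNND1. Cornified-envelope and keratinocyte differentiation genes behaved alike, with 18 of 24 lower and none higher (19 lower adjusted over the list alone). Their median was −0.81 (camera adjusted p = 4.44e-12; adjusted p = 0.0344 with an estimated correlation). After KRT13, the stress-associated keratin KRT16 fell 4.30-fold and the plakin PPL 4.04-fold.

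Luminal markers were also lower, with 8 of 12 fallen and none risen (9 lower and 1 higher adjusted over the list alone). The median was −0.51 (camera adjusted p = 0.000102; adjusted p = 0.157 with an estimated correlation). ERBB3, a receptor tyrosine kinase of the EGFR family, fell 3.02-fold, the simple-epithelial keratin KRT18 2.56-fold (−0.42 on the log2 scale on its other probe) and the pioneer factor FOXA1 2.42-fold. Basal and myoepithelial markers showed no common direction: of 14, 3 rose and 5 fell, over all genes and adjusted over the list alone, with a median of −0.10 (camera adjusted p = 0.553). Among them KRT15 fell 2.46-fold, whereas the membrane peptidase MME rose 2.83-fold and the oxytocin receptor OXTR 1.69-fold. Of 12 mammary stem and progenitor markers, 1 rose and 4 fell (3 and 5 adjusted over the list alone), with SOX9 down 2.84-fold and NOTCH3 2.11-fold (median −0.24, camera adjusted p = 0.0940; fry adjusted p = 0.00358, down).

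Mesenchymal markers moved the other way. Of 24 measured, 17 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.79 (camera adjusted p = 1.25e-10; adjusted p = 0.0528 with an estimated correlation). Besides COL6A3, the collagen cross-linking enzyme LOX rose 5.29-fold, and the matrix protein POSTN, not detected in vector cells, was at least 3.47-fold higher (2.24-fold with no background correction). Fibronectin (FN1) rose by a log2 fold change of 2.23 ± 0.07 (SE) and vimentin (VIM) by 1.99 ± 0.11. The transcription factors SNAI2 and TWIST1 rose by 1.53 ± 0.09 and 1.51 ± 0.15, and N-cadherin (CDH2) by 0.83 ± 0.09. The member that fell was the matrix protein TNC, by 0.81 ± 0.15. Fibroblast markers rose with them: 3 of 5 measured rose and none fell, over all genes and adjusted over the list alone (median 0.39, camera adjusted p = 0.0175; adjusted p = 0.157 with an estimated correlation). The call was also lost with no filter on dim probes (median 0.10), and the median was 0.59 without GNA13 array 3. Without vector array 1 or GNA13 array 1 or 2, fewer than 5 of these genes were measured and the list was not tested. The genes were DCN, FBLN1 (1.73-fold) and FAP (1.31-fold). The call of FAP was lost under median scaling (0.44) and without vector array 3 (0.32) or GNA13 array 2 (0.33), and other FBLN1 probes ranged from −0.13 to 0.35. The remaining members, COL1A1 and COL1A2, which the mesenchymal list also holds, did not pass.

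**Figure D2:**
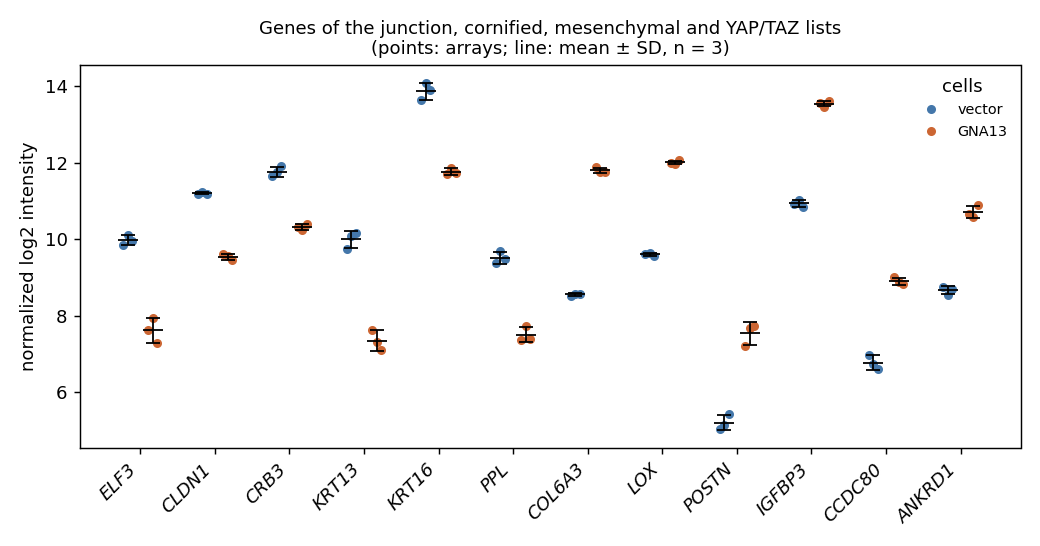
Normalized log2 intensity (vertical axis) of 12 genes from the junction, cornified-envelope, mesenchymal and YAP/TAZ lists (horizontal axis) in vector and GNA13 cells. Points are single arrays and lines are means ± SD (n = 3). ELF3 to PPL lie lower and COL6A3 to ANKRD1 higher on all 3 GNA13 arrays, by more than the spread within groups.

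Of 22 YAP/TAZ target genes, 11 rose, 3 fell and 8 did not pass (12 and 3 adjusted over the list alone). The median log2 fold change was 0.32 (camera adjusted p = 0.000294; adjusted p = 0.131 with an estimated correlation). IGFBP3, which binds insulin-like growth factors, rose 6.09-fold, CCDC80 4.37-fold (2.75-fold with no background correction, and 1.32 on the log2 scale on its other probe) and the muscle ankyrin-repeat gene ANKRD1 4.12-fold. The matricellular genes CCN1 and CCN2 rose by 1.74 ± 0.09 and 1.79 ± 0.13 on the log2 scale (SE). The members that fell were NUAK2, MYOF and DOCK5. Of 24 SRF/MRTF cytoskeletal targets, 3 rose and 8 fell (5 and 8 adjusted over the list alone), with a median of −0.19 (camera adjusted p = 0.0765; fry adjusted p = 0.0151, down). Smooth-muscle actin (ACTA2) rose 2.13-fold, while the myosin light chain MYL9 fell 2.77-fold and TAGLN 1.80-fold.

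Immediate early genes, EGFR ligands, integrins, matrix proteases and TGF-beta/SMAD targets did not pass with camera, which compares a list with other genes. Of 25 immediate early genes, 6 rose and 4 fell (8 and 4 adjusted over the list alone), among them KLF10 (1.68-fold higher) and ATF3 (1.54-fold higher). The median of −0.07 and mean of 0.04 differ in sign (camera adjusted p = 0.680; fry adjusted p = 0.0273, up). Of 5 EGFR ligands and relatives, TGFA fell 2.24-fold and NRG1 rose 1.98-fold on the probe used, over all genes and adjusted over the list alone (1 each), with a median of −0.10 (camera adjusted p = 0.697). The other NRG1 probe differed by only 0.03 on the log2 scale, and the authors' deposited table gives NRG1 a ratio of 1.04 (p = 0.221). Integrins were split, 4 of 17 higher and 4 lower, also adjusted over the list alone, with ITGA10 (6.53-fold), ITGA5, ITGB4 and ITGB5 higher and ITGB8, ITGB6, ITGA2 and ITGA6 lower (median 0.10, camera adjusted p = 0.553; fry adjusted p = 0.00358, up). ITGB8 was not detected in GNA13 cells and was at least 1.81-fold lower. With no background correction, ITGA10 was 3.49-fold higher. Of 25 matrix proteases and inhibitors, 4 rose and 8 fell (5 and 9 adjusted over the list alone). The gelatinase MMP9 fell 3.02-fold, ADAM8 2.55-fold and the urokinase receptor PLAUR 2.14-fold, while MMP10, ADAM9, SERPINE2 and PLAT rose (median 0.01, mean −0.18, camera adjusted p = 0.225; fry adjusted p = 0.00245, down). TGF-beta/SMAD targets had 6 of 17 higher and 2 lower (7 and 2 adjusted over the list alone), with the inhibitory SMAD6 and SMAD7 1.91-fold and 1.81-fold higher and the pseudoreceptor BAMBI 1.91-fold lower (median 0.19, camera adjusted p = 0.0713; fry adjusted p = 0.00294, up).

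Interferon-stimulated, NF-kB-linked and HLA genes had medians below 0, and each of these lists held more falls than rises. Of 28 interferon-stimulated genes, 15 fell and 3 rose (17 and 3 adjusted over the list alone), with a median of −0.43 (camera adjusted p = 1.13e-05; adjusted p = 0.0957 with an estimated correlation). IFI27 fell 5.42-fold, the exonuclease ISG20 2.61-fold and IFIT2 1.99-fold, while the members that rose were IFI44, IFIT1 and IFI6. IFI44L did not pass on the probe used (0.08 ± 0.11 SE), but its other kept probe, detected on 0 of 3 vector arrays and 3 of 3 GNA13 arrays, had a log2 intensity of 8.34 in GNA13 cells. Among 21 cytokines and chemokines linked to NF-kB, 10 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of −0.34 (camera adjusted p = 0.0264; adjusted p = 0.258 with an estimated correlation). The neutrophil chemoattractant CXCL8 fell 2.73-fold and the cyclooxygenase PTGS2 by 1.25 ± 0.09 on the log2 scale (SE). Against them, the granulocyte growth factor CSF3 rose 3.90-fold (2.17-fold with no background correction), the chemokine CCL20 3.13-fold, and the mitochondrial dismutase SOD2 also rose. This list's call was lost without vector array 1 (median −0.31). HLA class I and antigen-presentation genes had 4 of 11 lower and none higher, also adjusted over the list alone, with a median of −0.18 (camera adjusted p = 0.0220; adjusted p = 0.254 with an estimated correlation). The peptide transporter TAP1 fell 1.76-fold, and the others were PSMB10, HLA-E and HLA-C. Without vector array 3 the call of the list (median −0.19), HLA-E (−0.28) and HLA-C (−0.26) was lost. HLA-E also lost it without GNA13 array 1 (−0.31) or 3 (−0.32). HLA-C also lost it without vector array 1 (−0.33) or 2 (−0.33) and without GNA13 array 2 (−0.27) or 3 (−0.28). Both also lost it under median scaling (−0.35 and −0.25).

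Hypoxia and glucocorticoid lists had medians above 0 and the cholesterol list a median below 0. Of 34 hypoxia and glycolysis genes, 15 rose and 1 fell (15 and 3 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.000294; adjusted p = 0.126 with an estimated correlation). The carbonic anhydrase CA12 rose 3.96-fold, the enolase ENO2 2.52-fold and ANGPTL4 2.07-fold. The member that fell was ANKRD37. Glucocorticoid targets had 7 of 15 higher and 1 lower (8 and 3 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.0220; adjusted p = 0.227 with an estimated correlation). The transcription factor ZBTB16 rose 3.37-fold (2.06-fold with no background correction, other probes from 0.33 to 2.50 on the log2 scale), the kinase SGK1 2.39-fold and TSC22D3 2.14-fold, and ERRFI1 fell. Cholesterol biosynthesis genes had 10 of 19 lower and none higher, also adjusted over the list alone, with a median of −0.36 (camera adjusted p = 0.000671; adjusted p = 0.165 with an estimated correlation). HMGCS1, which makes the substrate of HMG-CoA reductase, fell 2.80-fold, and the decarboxylase MVD 1.66-fold. HMGCS1 lies in a stretch of 87 neighbouring genes whose median log2 fold change was −0.37 relative to all genes.

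Proliferation and stress lists did not pass with camera. Of 39 mitotic genes, 3 rose and 2 fell (1 and 2 adjusted over the list alone), with the kinase PLK1 1.61-fold lower and the kinesin KIF11 1.45-fold higher (median 0.09, camera adjusted p = 0.509). Of 33 DNA replication genes, 5 rose and 1 fell, also adjusted over the list alone, with thymidylate synthase (TYMS) 1.78-fold higher (median 0.10, camera adjusted p = 0.0765; fry adjusted p = 0.00411, up). Targets of p53 had 8 of 23 higher and 1 lower, also adjusted over the list alone, among them RRM2B (2.73-fold higher) and XPC (1.71-fold higher), with a median of 0.25 (camera adjusted p = 0.0885; fry adjusted p = 0.00132, up). Of 28 genes of the unfolded protein response and ATF4, 2 rose and 5 fell, also adjusted over the list alone. The lipoprotein receptor VLDLR rose 3.04-fold and the pseudokinase TRIB3 fell 1.56-fold (median −0.03, mean 0.02, camera adjusted p = 0.680). Of 18 NRF2 and metallothionein genes, 6 rose and 2 fell, also adjusted over the list alone. The metal-binding proteins MT1X and MT1G rose 3.28-fold and 2.62-fold (median −0.04, mean 0.20, camera adjusted p = 0.509; fry adjusted p = 0.00877, up). Of 29 oxidative phosphorylation genes SDHA alone changed, also adjusted over the list alone, falling 1.42-fold (median 0.05, camera adjusted p = 0.553). It lies in the same stretch of neighbouring genes as HMGCS1. Haematopoietic markers had 3 of 8 lower and none higher, also adjusted over the list alone, with the actin-binding protein CORO1A 2.54-fold lower (median −0.20, camera adjusted p = 0.225; fry adjusted p = 0.00721, down). Only 3 of 14 endothelial and neural markers were measured, too few for a list test, and of these ENO2 rose while TUBB3 (−0.71 ± 0.08 SE) and MAP2 (−0.46 ± 0.10) fell. The call of MAP2 was lost under median scaling (−0.39) and with the mean of its probes (−0.28).

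**Figure D3:**
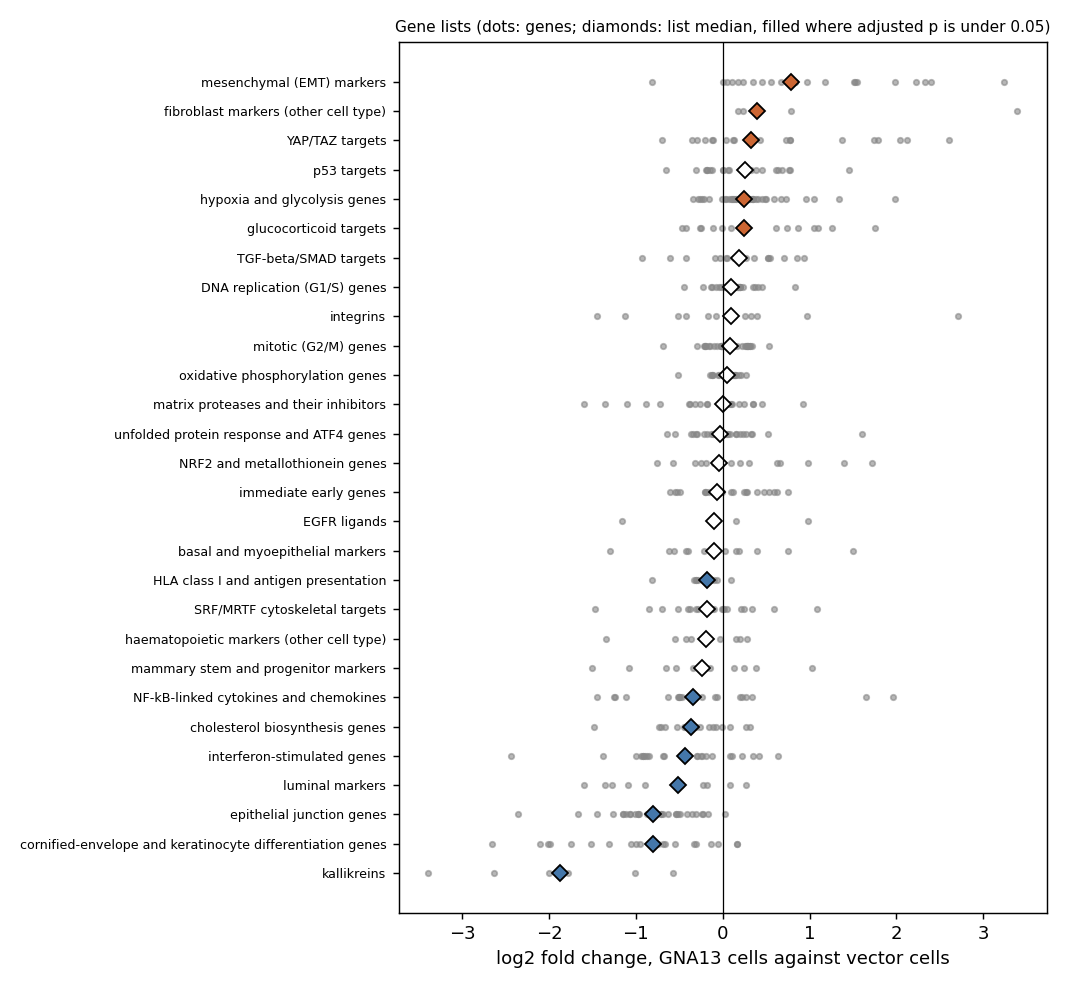
Log2 fold change of GNA13 against vector cells (horizontal axis) for the genes of each reported list that was tested (vertical axis). Dots are genes and diamonds are list medians, filled where the camera adjusted p with the preset correlation was under 0.05. The kallikreins have the lowest median (−1.88) and the mesenchymal markers the highest (0.79).

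The authors' deposited table gave the same contrast from an analysis that held further arrays. Its ratio compares the same groups of cells, so a shared direction is no independent support. Of the 3105 changed genes, 2832 were found there and 2825 of these (99.8%) had a ratio on the same side of 1 in the authors' deposited table. Many folds are smaller there. Of 102 changed genes taken by the naming rule and found there, 24 had a fold in the authors' deposited table over 1.5 times smaller than the fold or bound given here, and none one over 1.5 times larger. In the authors' deposited table RTN1 was 1.93-fold higher (at least 8.08-fold here), KLK8 2.57-fold lower (at least 8.22-fold here), DCN 3.66-fold higher (10.5-fold here), ACKR1 11.03-fold higher (at least 23.6-fold here), GABRP 2.92-fold lower (at least 5.10-fold here) and KLK10 3.77-fold lower (6.23-fold here). COL6A3 was nearer, 7.56-fold higher in the authors' deposited table. With no background correction here, ACKR1 (10.7-fold) and GABRP (2.93-fold) came near the authors' values. RTN1 (3.84-fold), KLK8 (3.88-fold), DCN (5.69-fold) and KLK10 (4.73-fold) still had larger folds than the authors'. Each of these genes is read here by its brightest probe. Their other probes changed less, by 0.30, −0.76, 2.59 and −0.06 on the log2 scale with background correction. Whether this accounts for the gap was not tested. For GNA13, the authors' deposited table held a ratio of 1.14 and a p of 0.0578.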

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

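The probe test given here was chosen only after the annotation had been seen. Among 4721 detected probes for which the platform annotation lists no gene, 316 changed between vector and GNA13 cells, 150 higher and 166 lower in GNA13 cells (limma, Benjamini-Hochberg adjusted p under 0.05 over these probes). This is 6.69% of these probes, below the 27.4% of named genes that changed. The shares are not fully alike, since they were adjusted apart and each named gene was read by its brightest probe only. They are listed because the comparisons above do not use them. Their genes are not named here, and no biological explanation was tested.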

How the results depend on the processing

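No gene taken by the naming rule and no list past the threshold changed direction in any alternative where it had a value. Genes detected in only 1 group and by no other probe had no value without an array of that group or under the stricter filter. Among them were ACKR1, ROS1, WNT5A, CAPN13, FGFBP1, GABRP, KLK11 and ITGB8. Other genes named were followed, if at all, only through the run with no background correction. Median scaling in place of quantile normalization gave 2007 changed genes, 1926 of them among the 3105, with 859 lower, and turned the direction of the uncalled oxidative phosphorylation list in camera (median 0.013). A minimum fold of 1.5 left 1239 genes, and the authors' deposited table held 6605 genes at its own unadjusted p under 0.05, with more arrays in its analysis. Camera with an estimated correlation called 3 lists and fry 23. With an estimated correlation, which leaves medians as they are, the calls of the YAP/TAZ (0.32), NF-kB (−0.34), interferon (−0.43), HLA (−0.18), mesenchymal (0.79), luminal (−0.51), hypoxia (0.25), cholesterol (−0.36), glucocorticoid (0.24) and fibroblast (0.39) lists were lost. The fibroblast list also lost its call with no filter on dim probes (0.10), and had fewer than 5 measured genes, hence no value, under the stricter filter and without vector array 1 or GNA13 array 1 or 2. The kallikreins also had no value under the stricter filter, for the same reason. Leaving out each array in turn gave 977 to 1414 genes higher, with the lowest counts without GNA13 array 1 (977), 2 (986) or 3 (985). It gave NF-kB medians of −0.42 to −0.31 (call lost without vector array 1, −0.31) and HLA medians of −0.26 to −0.17 (call lost without vector array 3, −0.19). Among genes taken by the naming rule, 59 calls were lost over all genes and alternatives with a value, most often under median scaling or without an array. In further lists, 22 calls were gained. Where a call or count changed, the cause was not tested, except that a left-out array means fewer samples and can change the probe used for a gene, as for KLK8 and RTN1. Arrays with the same number did not deviate together (correlations of 0.00, 0.01 and −0.03 over genes). This gave no sign of pairing by number, but cannot exclude that same-numbered samples were handled together. With the replicate number as a block, 2527 genes changed. A slide block was not run, because the columns name no slides. Without the stretch of 87 neighbouring genes, chosen after seeing the data, 3037 genes changed. Low signal over background limits KLK1, KLK11 and other dim genes.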

Other observations

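All tests of explanations given here were chosen after the results were seen, except the splits of the arrays, which were planned. The changed genes named next lie outside the lists and were chosen after their values were seen. The growth factor FGF2 rose by a log2 fold change of 2.90 ± 0.14 (SE, n = 3 per group), from a mean log2 intensity of 5.90 to 8.80 (1.77 with no background correction). The matrix protein ABI3BP, not detected on any vector array, was at least 5.39-fold higher (2.87-fold with no background correction). The transglutaminase TGM2 rose by 2.46 on the probe used and by 0.29 on the other. Among the falls were the interleukin-1 receptor antagonist IL1RN (log2 fold change −2.22, and −1.42 with no background correction), the epithelial transcription factor GRHL3 (−2.02 and −1.33) and the tight-junction protein CGN (−1.76).

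Neighbouring genes also moved together. In the gene order of assembly GRCh38.p14, ACKR1 and CADM3, with the largest rises, were adjacent among the genes tested. Of the 100 largest rises, 4 pairs were adjacent, against a mean of 0.851 and a highest value of 5 in 1000 random lists. No explanation of this was tested.

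Mesenchymal genes were higher and epithelial genes lower in the GNA13 arrays. Fibroblasts mixed into the cultures would bring their most abundant transcripts, but the median difference of COL1A1, COL1A2, COL3A1, LUM, PDGFRA and PDGFRB was 0.0539 on the log2 scale (SD over genes 0.161). The brightest stood at 6.08 in GNA13 cells and all but COL1A1 and COL1A2 were undetected in both groups, while DCN rose by 3.39. The set was chosen after COL1A1 and COL1A2 were seen not to pass, and leaves out FBLN1 and FAP, which rose. Values this near background do not settle whether fibroblasts were present. Dilution by any cells without epithelial genes would lower epithelial genes alike, but the junction list's median was −0.59 relative to that of 7 epithelium-restricted basal genes (two-sided permutation p = 0.00379 over genes, which are not independent). These 7 genes were picked after the medians of both lists had been seen, so a gap was known beforehand. The permutation p thus does not decide against dilution. A change of state of the epithelial cells with GNA13 stays open as a hypothesis, and so does a difference between separately selected cell populations that has nothing to do with GNA13, which the design cannot separate from it. Of the 10 splits of the 6 arrays, 1, the real one, gave as many as 3105 changed genes (limma), and the highest of the others gave 0. Each other split mixes the groups and adds their difference to the spread within, which by itself favours few changed genes. For the lists, 1 split gave as many as 13 past the threshold and the highest of the others gave 6, and 10 splits are too few for a share under 0.05.

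Both GNA13 probes differed little between cells named for the presence or absence of introduced GNA13. Too little precision is argued against by the upper 95% bound of the fold, 1.39 over both probes. Saturation is argued against by the brightest GNA13 signal, 2.37% of the dimmest array's maximum. Probes outside the transferred sequence may explain it, but 0 of the probes have a known position in the transcript, so this cannot be told apart from a small rise in the transcript.

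A stretch of 87 neighbouring genes tested, from CCDC127 to ISL1, was lower in GNA13 cells, with a median log2 fold change of −0.37 relative to all genes and 53 changed genes, of which 49 fell. Chance order is argued against by a running median over 41 genes of 0.38 from the median of all genes, against at most 0.31 in 100 permuted orders. Of its genes, IL7R and CDH10, chosen after their values were seen, rose by 1.10 and 1.60 (0.85 and 0.78 with no background correction). A difference in DNA copy number between the cell populations may lower such a stretch evenly, and the interquartile range of its fold changes was 0.86 times that of other genes, as an even shift would leave it. Any other cause of a modest shared fall could leave the same range, so the ratio does not single out copy number. The 3 GNA13 arrays gave medians of −0.38 to −0.35, and copy number itself was not measured here.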
